A study of Bos taurus with 24 samples.

How the data were processed

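RNA-seq was run on liver and mammary biopsies of multiparous Holstein cows, a dairy breed, in the non-lactating dry period of late gestation. Per the labels' protocols and the series description, milking ceased 60 d before expected calving. From 35 d before expected calving the cows were kept in 1 barn under 16 h of light and 8 h of dark at 150 lx. Control cows had a constant cycle, and for phase shift cows the cycle was moved by 6 h every 3 d. Both tissues were sampled 21 d before expected calving, after 2 weeks of treatment and at least 5 shifts. The treatments were housed in separate partitions of the barn, so partition and treatment cannot be told apart in any comparison. The hour of the biopsies is not given in the sources used here.

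Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into libraries and sequenced as paired reads. Per the submitters' processing notes, the authors trimmed reads with Trimmomatic 0.36, aligned them with STAR 2.5.2b to the cattle build ARS-UCD1.2, counted them per gene with featureCounts from Subread 1.5.2, and used DESeq2. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may be divided between genes. For each tissue the authors deposited whole-number read counts per Ensembl gene ID, a normalized table and a table of regularized log values. The raw count tables hold 27607 gene IDs, of which 22503 had at least 1 read in liver and 23653 in mammary. The authors' normalized values are a signal on the count scale: tested on the files, each equals the raw count divided by 1 size factor per library, and these factors equal DESeq2's median-of-ratios factors. The deposited normalized tables keep the 14333 liver and 15840 mammary genes whose counts summed over the 12 libraries of the tissue exceed 120; the lowest sum kept was 121 and the highest left out was 120. The regularized log values deposited by the authors are on the log2 scale and cover the same genes. Raw counts were used for every main test, and the regularized log values for an alternative.

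The deposited tables hold 24 libraries, 12 per tissue, with 6 control and 6 phase shift libraries in each. The library names carry 13 cow labels, 6 control and 7 phase shift, although the series description gives 6 phase shift cows. Cows with libraries of both tissues number 11. Phase shift cow 25 has a liver library without a mammary library, and phase shift cow 21 has a mammary library without a liver library. Within a tissue, replicates are separate cows, and every p-value for a treatment comparison within a tissue refers to cows. The main fit for the tissue difference takes the libraries of a cow as independent, so its p-values refer to libraries. Cows were assigned to treatments by blocking on lactation number and previous yield, but no label gives a cow's block.

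Total counts, given in M (mega counts), ran from 7.68 to 26.9 M in liver and from 5.05 to 13.1 M in mammary. In each tissue, phase shift was compared with control by edgeR's quasi-likelihood F test with robust dispersion (edgeR 4.0.16, R 4.3.3), trimmed-mean (TMM) scaling, genes kept by filterByExpr with a minimum count of 10 and a minimum total of 15, and Benjamini-Hochberg adjustment at a threshold of 0.05. Whether the response differed between tissues was tested as an interaction in 1 edgeR fit to all 24 libraries, which also gave mammary against liver averaged over treatments. Log2 fold changes are phase shift minus control unless another direction is given, and their 95% confidence intervals come from the same fits. Log2 CPM, from counts scaled to library size, used a prior count of 2. Library measures were compared by exact two-sided permutation of the treatment labels over 924 assignments, for which the smallest possible p is 0.00216. The tests were checked on simulated data drawn from the means and library sizes of the real samples, with 200 genes changed by a known fold. A single data set was drawn per fold and comparison, in which genes varied independently and no library was made to stand apart. The shares recovered hold for that setting, and may differ with another number of changed genes. At 1.5-fold, edgeR recovered 0% of the changed genes in liver and 0% in mammary. At 2-fold it recovered 69% of 200 in liver and 29.5% of 200 in mammary, and at 4-fold 89.5% and 85%. For the tissue difference it recovered 15.5% at 2-fold and 69% at 4-fold. DESeq2 (1.42.0) recovered 26.5% at 1.5-fold in simulated liver data, with 18.5% of its calls false, and 78% at 2-fold, with 13.3% false. In simulated mammary data it recovered 9% at 1.5-fold, with 33.3% of its calls false, and 54% at 2-fold, with 16.3% false.

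No symbols are used. The gene IDs come without names in the deposited tables, and the RefSeq gene table available (assembly ARS-UCD2.0, 37063 genes) lists an Ensembl ID for 0 of its genes, so 0 of the IDs matched. The 44 gene lists fixed before the data were examined, which held clock, metabolic, milk and cell type marker genes, could not be tested for that reason, nor could the planned clock index. The planned rule for named genes took clock genes and genes with symbols, and could not be applied in full. In its place, with 0 genes past the threshold, the 2 IDs of smallest unadjusted p in each direction with a mean of at least 1 on the log2 CPM scale are given for each tissue, and 1 ID per direction for the tissue difference. Gene groups were instead taken from the data: genes at least 8-fold higher in 1 tissue and past the threshold of mammary against liver (tissue-enriched), and genes under 2-fold apart (shared). These groups were tested with fry, with camera at a preset correlation of 0.01 and with camera at an estimated correlation (limma 3.58.1). The choice of groups, the comparison of mammary with liver, the count of genes whose treatment groups do not overlap, and the matching of libraries from the same cow were added after the data were examined.

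Alternatives were other scaling (DESeq2 size factors), no filter or a mean of at least 1 CPM, DESeq2's Wald test, limma-voom with and without sample quality weights, limma-trend on the regularized log values, an adjusted p of 0.1, the number shared by a control and a phase shift cow as a block, the cow as a block for the tissue difference, and each replicate left out in turn. Fits without the libraries that stand apart were added after the data were examined. Other splits of the cows into 6 and 6 were refitted for 100 of the 462 possible splits, the real grouping included. For the results that join the tissues, the liver library of phase shift cow 25 and the mammary library of phase shift cow 21 were moved together, as if from 1 cow, so those splits hold under that assumption.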

Results

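The data set holds 24 rRNA-depleted RNA-seq libraries from 13 labelled Holstein cows sampled 21 d before expected calving, 12 from liver and 12 from mammary gland. In each tissue, 6 libraries came from cows under a constant light-dark cycle (control) and 6 from cows whose cycle had been moved by 6 h every 3 d for 2 weeks (phase shift). The series asks how disruption of circadian timing in late gestation changes the transcriptomes of liver, which handles much of the cow's metabolic load around calving, and of the mammary gland as it prepares for lactation. The design implies a comparison of phase shift with control in each tissue, and a comparison of the responses of the tissues.

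Liver libraries held a mean of 8.96 M counts in control cows (SD 1.5, n = 6) and 12.7 M in phase shift cows (SD 7.29, n = 6). The group difference was within the spread between cows (exact two-sided permutation p = 0.260). The deepest liver library, phase shift cow 26, had 26.9 M counts and the shallowest, phase shift cow 19, had 7.68 M. Mammary libraries held 7.79 M counts in control cows (SD 2.81, n = 6) and 8.11 M in phase shift cows (SD 2.19, n = 6; exact permutation p = 0.848). Number of genes detected, share of the 10 most abundant genes and rank correlation with the other libraries of the tissue also did not separate the treatments. The Benjamini-Hochberg adjusted exact permutation p over these measures, depth included, was 0.991 for each of the 8 tests.

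In liver, the first principal component held 34.1% of the variance and set the library of phase shift cow 22, at a score of 94.9, apart from the other 11, which lay between -9.77 and -7.06. Within that narrow range, 5 of 6 control libraries, at -9.77 to -9.14, lay below the 5 phase shift libraries, at -8.70 to -7.06, and control cow 26, at -7.91, lay among them. In mammary, the first component held 41.8% and set apart the libraries of phase shift cow 21, at 78.9, and control cow 26, at 121. The other 10 mammary libraries lay between -37.1 and -4.13. The 10 most abundant genes took 25.0% of the counts of phase shift cow 21 and 26.2% of those of control cow 26, against 9.19 to 16.4% in the other mammary libraries.

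**Figure D1:**
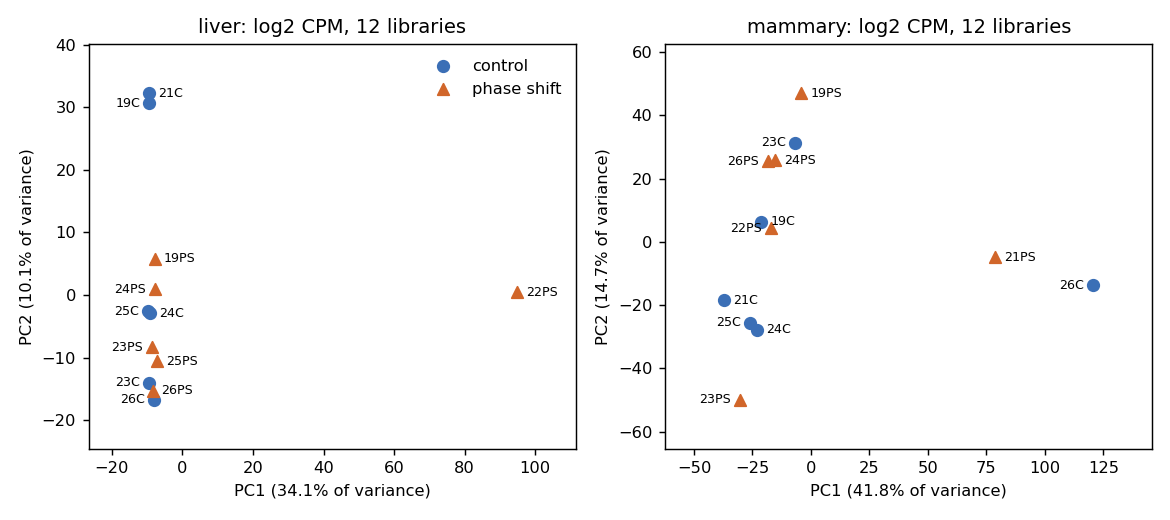
First and second principal components of log2 CPM in liver and mammary, 1 point per library, with control cows as circles and phase shift cows as triangles. Liver of phase shift cow 22 (score 94.9) and mammary of phase shift cow 21 (78.9) and control cow 26 (121) lie apart along the first component.

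In liver, no gene was past the threshold between phase shift and control cows in the edgeR test. Of 13752 genes tested, 0 passed an adjusted p of 0.05 and 0 passed 0.1, and the lowest adjusted p was 0.469. Unadjusted p was under 0.05 for 813 genes, 434 higher and 379 lower under phase shifts, where 688 of the tested genes would be so by chance. The median standard error of a log2 fold change was 0.16, and for 11580 genes (84.2%) the 95% confidence interval lay within a 2-fold change in either direction. Simulated 2-fold changes in these libraries were recovered for 69% of genes and simulated 1.5-fold changes for 0%, so changes of 1.5-fold were not detectable by this test.

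The liver gene of smallest p was higher under phase shifts. ENSBTAG00000002827 had a mean of 78.4 CPM in control cows (SD 4.43, n = 6) and 106 CPM in phase shift cows (SD 7.64, n = 6), with all 6 phase shift cows above every control cow. Its log2 fold change was 0.43 (SE 0.071), with an edgeR adjusted p of 0.469. Its log2 fold change in mammary was -0.44, and the edgeR interaction adjusted p was 0.779. ENSBTAG00000044179 had 55.8 CPM in control cows (SD 10.2) and 88.7 CPM in phase shift cows (SD 14.9), and 4 of 6 phase shift cows lay above every control cow (log2 fold change 0.67, SE 0.14, edgeR adjusted p = 0.734). Among genes lower under phase shifts, ENSBTAG00000044659 had 11.9 CPM in control cows (SD 3.77) and 6.56 CPM in phase shift cows (SD 0.866), with 6 of 6 phase shift cows below every control cow (log2 fold change -0.85, SE 0.19, edgeR adjusted p = 0.734). ENSBTAG00000009085 had 75.7 CPM in control cows (SD 4.72) and 59.5 CPM in phase shift cows (SD 5.67), again with 6 of 6 below every control cow (log2 fold change -0.35, SE 0.079, edgeR adjusted p = 0.734). The deposited tables do not pair these IDs with names.

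The count of liver genes depended on the tool and, within edgeR, on the setting. With the shared number as a block edgeR called 2 genes, and without control cow 26 it called 1. DESeq2 called 16 liver genes, 14 higher and 2 lower under phase shifts, and had 980 at unadjusted p under 0.05, while limma-voom called 0. The edgeR fold changes of all 16 had the same direction, with unadjusted p under 0.05 and adjusted p between 0.469 and 0.734. ENSBTAG00000002827 had a DESeq2 adjusted p of 1.51e-05, ENSBTAG00000044179 of 0.00681 and ENSBTAG00000009085 of 0.0357, while DESeq2 gave none for ENSBTAG00000044659. DESeq2's filter on mean expression and its check for extreme counts left 18613 of the 22503 genes with a read, this one included, without an adjusted p. Over all settings tried, the adjusted p of these genes ran from 1.51e-05 to 0.849, from 0.000319 to 0.849 and from 0.0199 to 0.849. The treatment groups did not overlap for 3 of the 16 genes. Without the liver library of phase shift cow 22, which stands apart, DESeq2 called 30 genes, 18 higher and 12 lower, and 15 genes were called both with and without it.

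**Figure D2:**
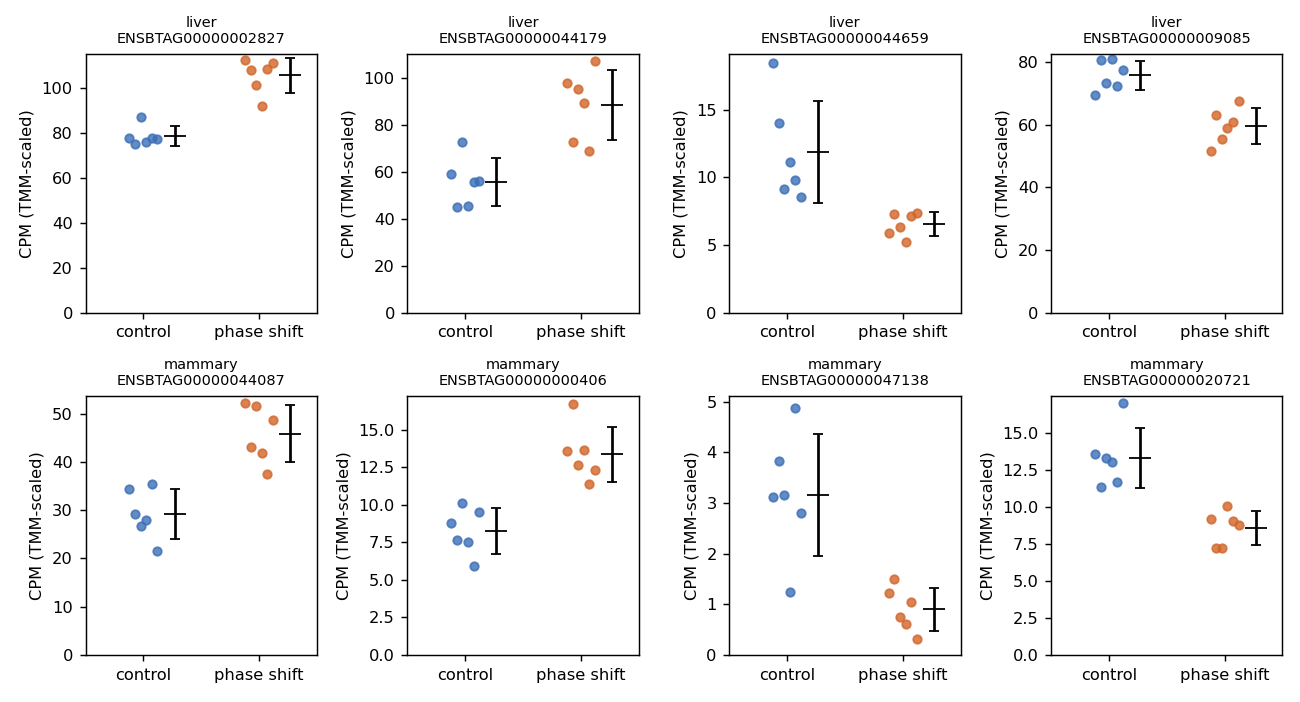
TMM-scaled CPM per cow for the genes of smallest p in each direction, liver above and mammary below, in 6 control and 6 phase shift cows. Black marks give the mean and SD; in liver ENSBTAG00000002827, the phase shift mean of 106 CPM compares with 78.4 CPM in control cows, and none of these genes passed the edgeR threshold.

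In mammary, no gene was past the threshold between phase shift and control cows in edgeR, DESeq2 or limma-voom. Of 15547 genes tested, 0 passed in edgeR, and the lowest adjusted p was 0.923. Unadjusted p was under 0.05 for 739 genes in edgeR, 362 higher and 377 lower, where 777 would be so by chance, and for 985 genes in DESeq2. The edgeR count was 1251 without phase shift cow 23, 474 without phase shift cow 26 and 168 with the shared number as a block. Limma-voom with sample quality weights gave 1724. The median standard error of a log2 fold change was 0.23, and the 95% confidence interval lay within a 2-fold change for 11076 genes (71.2%). Simulated 2-fold changes in mammary were recovered for 29.5% of genes and 4-fold changes for 85%. Without the libraries of phase shift cow 21 and control cow 26, edgeR called 0 genes and DESeq2 called 19, 4 higher and 15 lower under phase shifts.

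The mammary genes of smallest p did not include those named in liver. ENSBTAG00000044087 had 29.2 CPM in control cows (SD 5.13, n = 6) and 45.8 CPM in phase shift cows (SD 5.88, n = 6), with 6 of 6 phase shift cows above every control cow (log2 fold change 0.65, SE 0.14, edgeR adjusted p = 0.923). ENSBTAG00000000406 had 8.25 CPM in control cows (SD 1.52) and 13.4 CPM in phase shift cows (SD 1.83), also with 6 of 6 above (log2 fold change 0.70, SE 0.16, edgeR adjusted p = 0.923). ENSBTAG00000047138 had 3.17 CPM in control cows (SD 1.2) and 0.903 CPM in phase shift cows (SD 0.427), with 5 of 6 phase shift cows below every control cow (log2 fold change -1.79, SE 0.40, edgeR adjusted p = 0.923). This gene was near the floor, at 0.324 to 1.49 CPM in phase shift cows. It was filtered out in edgeR without control cow 26, and its log2 fold change was -0.43 on the regularized log values. ENSBTAG00000020721 had 13.3 CPM in control cows (SD 2.01) and 8.57 CPM in phase shift cows (SD 1.13), with 6 of 6 below (log2 fold change -0.63, SE 0.15, edgeR adjusted p = 0.923). In DESeq2 without the libraries of phase shift cow 21 and control cow 26, ENSBTAG00000044087 and ENSBTAG00000047138 passed the threshold, each with an adjusted p of 0.0437. Over all settings tried, the lowest adjusted p was 0.107 for ENSBTAG00000000406 and 0.354 for ENSBTAG00000020721, and the highest was 1 for each of the 4 genes.

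Gene groups enriched in a tissue did not differ detectably between treatments. Of the genes tested in liver, 1186 were liver-enriched, and their median log2 fold change under phase shifts was -0.0095, with 570 of them higher. The 221 mammary-enriched genes tested in liver had a median of -0.083, with 87 higher, and the 8765 shared genes had a median of 0.017. Without the liver library of phase shift cow 22 these medians were 0.0095 for liver-enriched, -0.042 for mammary-enriched and -0.00099 for shared genes, so the first and last turned sign. Both also turned sign with the shared number as a block, at 0.0056 for liver-enriched and -0.00095 for shared genes. In mammary, the 1280 mammary-enriched genes had a median of 0.070, with 713 higher, and this median was -0.014 without the libraries of phase shift cow 21 and control cow 26. The 542 liver-enriched genes tested in mammary had a median of -0.081. In the mammary library of phase shift cow 21, transcripts abundant in liver and near 0 in the 10 mammary libraries that do not stand apart stood at a median of 1.98% of their liver level. In mammary the 9336 shared genes had a median of -0.00034. Without the libraries of phase shift cow 21 and control cow 26, these medians were -0.047 for liver-enriched and 0.00087 for shared genes. The fry test gave an adjusted p of 0.982 for each of the 6 combinations of group and tissue. The lowest adjusted p from camera was 0.162 at the preset correlation and 0.658 with an estimated correlation, so no group passed in either.

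The response to phase shifts was not detectably different between tissues for any gene in edgeR. Of 16656 genes tested for the interaction, 0 passed, the lowest adjusted p was 0.737, and 1111 had an unadjusted p under 0.05 where 833 would be so by chance. This fit takes the libraries of a cow as independent, and with the cow as a fixed block in edgeR, over the 11 cows with both tissues, the number was 694. In limma-voom it was 616 without a block and 672 with the cow as a random block. In each of these fits 0 genes passed the threshold. ENSBTAG00000042518 had a log2 fold change of -0.76 in liver (SE 0.29) and 0.80 in mammary (SE 0.22), a difference of 1.58 (SE 0.35, edgeR adjusted p = 0.737). ENSBTAG00000009804 had a log2 fold change of 0.30 in liver (SE 0.086) and -0.25 in mammary (SE 0.087), a difference of -0.53 (SE 0.12, edgeR adjusted p = 0.737). DESeq2 called 1 gene for the difference and had 1171 at unadjusted p under 0.05. This gene, ENSBTAG00000017335, had a difference of 0.73 (SE 0.15, DESeq2 adjusted p = 0.0189), with adjusted p up to 0.9998 in other settings. It was chosen after its values were seen, as the single call. The 95% confidence interval of the difference lay within 2-fold for 49.1% of genes, and simulated 2-fold differences were recovered for 15.5% of genes.

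**Figure D3:**
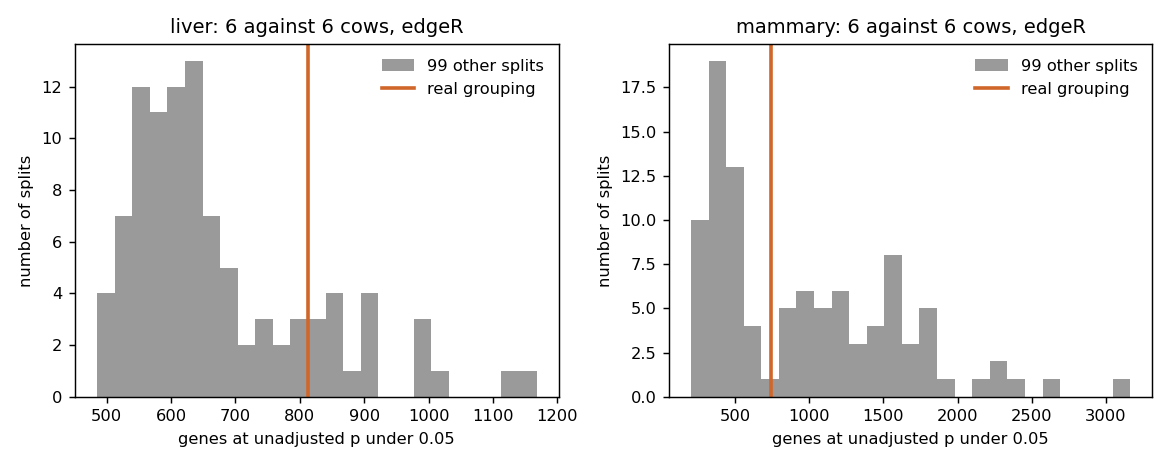
Number of genes at unadjusted p under 0.05 in edgeR in 99 other splits of the cows into 6 and 6 (grey bars, counted as splits) and in the real grouping (line), for liver and mammary. The real grouping gave 813 genes in liver and 739 in mammary, and other splits reached 1168 and 3165.

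With all libraries, fold changes in liver and mammary showed no correlation across genes beyond that of other splits of the cows. Over the 12940 genes tested in both tissues, Pearson's r between the log2 fold changes was 0.00146 and Spearman's rho was 0.028, with the same sign for 51.6% of genes. These are correlations across genes, which are not independent replicates. Other splits of the cows, 99 in number, gave r between -0.0276 and 0.126 with a mean of 0.0295 (SD 0.0331). In the real grouping r was 0.0569 without control cow 26 and 0.0818 without the libraries that stand apart, and no splits were run for those fits. Unadjusted p was under 0.05 in both tissues for 48 genes, where 36.5 would be so if the tissues were independent, and 22 of the 48 had the same direction.

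The tissues themselves differed in most genes. Averaged over treatments, 12132 of 16656 genes (72.8%) passed the edgeR threshold between mammary and liver, 6485 higher in mammary and 5647 lower. At least 8-fold differences past the threshold were seen for 1305 genes in favour of mammary and 1188 in favour of liver, and 9523 genes were under 2-fold apart.

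Libraries of the same cow resembled each other across tissues, within the differences between tissues. Log2 CPM of the 300 genes most variable in both tissues, chosen without the labels, was centred within each tissue and correlated between liver and mammary libraries. For the 11 cows with both tissues, the correlation across genes with the cow's own other library was 0.178 to 0.419 with a mean of 0.291, against a mean of -0.0274 between different cows. The liver library correlated best with the mammary library of its own cow in 11 of 11 cows. The mammary library correlated best with the liver of its own cow in 10 of 11, the exception being control cow 26. The mean own-cow correlation exceeded that of all 100000 random pairings (one-sided permutation p = 1e-05, the smallest these permutations can give).

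**Figure D4:**
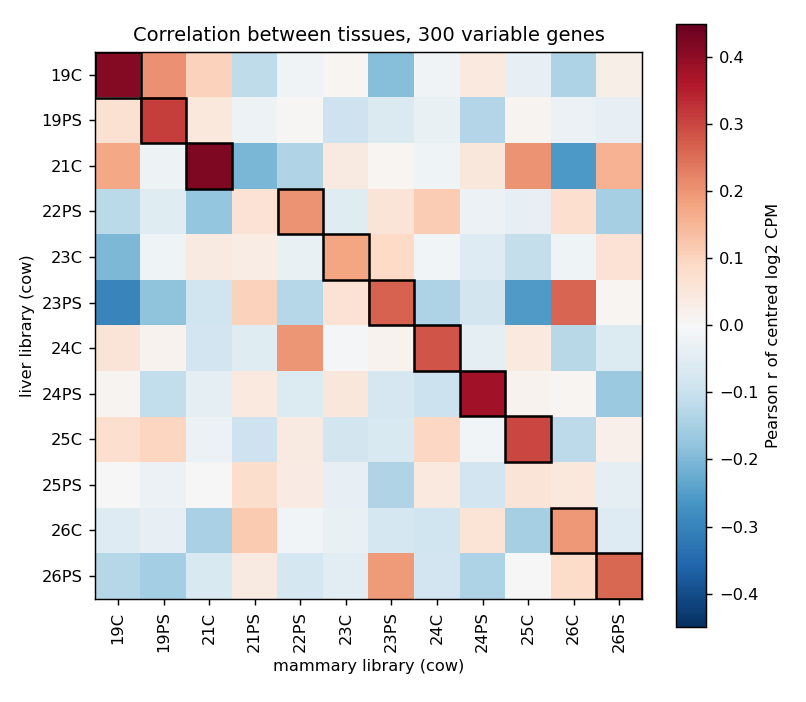
Pearson correlation across 300 genes between each liver library (rows) and each mammary library (columns), by cow label, with values from the same cow outlined. Own-cow values run from 0.178 to 0.419, and the mean between different cows is -0.0274.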

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

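The tests for RNA of another tissue, for depth and for abundant genes were chosen after the result was seen, and the test for a state shared by the tissues of cow 22 before. A sample was singled out where its gap to the nearest sample of its group, as a share of the range of the 6, exceeded Dixon's 95% critical value. This happened 10 times over 36 groups of 6 values, where about 1.8 would be expected by chance.

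The liver library of phase shift cow 22 stood apart by its score of 94.9 on the first component, where the next phase shift cow had -7.06, and by a median rank correlation with the other livers of 0.928, where the next had 0.973. In this library 248 genes were at least 8-fold above the median of the other livers and held 10.9% of its counts, against at most 0.774% in another liver, while the 21 genes at least 8-fold below compare with up to 17 in another liver. Low depth was argued against by its 8.94 M counts, between the 7.68 and 26.9 M of the other livers, and RNA of mammary tissue by the 81 mammary transcripts that summed to 24.1 CPM, within the 20.3 to 44.1 CPM of the other livers. A state of the cow that raises the same genes in both tissues was also argued against: the raised genes had a median log2 excess of -0.048 in the mammary library of the same cow, with quartiles of -0.19 and 0.11. Of the 248 genes, 5 had a mean under 1 CPM in the mammary libraries that do not stand apart, so nearly all were also expressed in mammary. A state that acts through other genes in mammary was not tested. RNA of a further cell type and a local state of this liver remain open, since without gene names no markers could be tested.

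The mammary libraries of phase shift cow 21 and control cow 26 stood apart by first-component scores of 78.9 and 121, where the next in their groups were -4.13 and -6.94, and by median rank correlations of 0.899 and 0.860, where the next were 0.946 and 0.955. They resembled each other: 295 genes were at least 4-fold raised in both, where 22.0 would be if they were independent, 125 were at least 4-fold lower in both, where 14.7 would be, and their rank correlation was 0.928. A few abundant genes taking the counts were argued against, since without the 50 most abundant genes of each library, and scaled to the rest, 749 and 1485 genes were still 4-fold apart from the other libraries (831 and 1855 with them), against at most 188 in the other 10. RNA of liver was argued against as the source of what they share, since the excess was within 5% of the liver level for only 5 of the 295 genes. As there is 1 control and 1 phase shift cow, treatment does not separate them from the rest, and the stage of the gland and the tissue within the biopsy remain open and were not tested.

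The mammary library of phase shift cow 21 also carried liver transcripts at a nearly even rate, which may reflect liver RNA in that library. The 175 transcripts with a mean above 50 CPM in liver and below 1 CPM over the 10 mammary libraries that do not stand apart were, in this library, at a median of 1.98% of their liver level, with 80% of them between 1.15 and 3.38%, and their excess rose with the level in liver (Spearman's rho of 0.868 across genes). In those 10 mammary libraries the median was between -0.0446 and 0.00236% of the liver level and rho was at most 0.244. In control cow 26 the median was 0.0731% and rho 0.298, while the upper decile was 2.12% and the transcripts summed to 979 CPM. Carry-over at biopsy, extraction or sequencing would each give such a pattern and cannot be separated with these tables, and no biological explanation was tested.

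Other samples singled out were the liver libraries of control cow 24, with 12 M counts where the next control cow had 8.69 M, and of phase shift cow 26, with 26.9 M where the next had 13.0 M. The liver library of control cow 26 had a first-component score of -7.91, where the next control cow had -9.14. Control cow 23 had 87.2 CPM of ENSBTAG00000002827 in liver, where the next control cow had 77.7 CPM.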

How the results depend on the processing

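Fits without libraries that stand apart were chosen after seeing the data, as were the counts at unadjusted p and the comparison of mammary with liver. In liver, 0 genes were called in edgeR with other scaling, no filter, a mean of at least 1 CPM or an adjusted p of 0.1, and in limma-voom with or without quality weights and limma-trend. DESeq2 called 16, or 30 without phase shift cow 22; the cause was not tested. Leaving out 1 cow gave 0 to 1 liver genes (1 without control cow 26) and 0 mammary genes in each of 12 fits. In mammary, every setting gave 0 except DESeq2 without the libraries that stand apart, with 19, and for the tissue difference every setting gave 0 except DESeq2, with 1; the causes were not tested. Shared numbers showed no pairing of cows in mammary, where same-number correlations were -0.384 to 0.165. There, 0 of 5 pairs correlated best with each other. In liver, pairing was not settled: same-number correlations were -0.0845 to 0.101, and 2 of 5 pairs correlated best with each other. With the number as a block, 2 liver and 0 mammary genes were called, and with the cow as a block the tissue difference stayed at 0. Mammary genes at unadjusted p under 0.05 went from 739 to 168 with the number as a block, 1724 with limma-voom quality weights, 1251 without phase shift cow 23 and 474 without phase shift cow 26. For the tissue difference they went from 1111 to 694 in edgeR with the cow as a fixed block (11 cows), and were 616 in limma-voom and 672 in limma-voom with the cow as a random block, and in liver they went from 813 to 1301 without a filter. The correlation of fold changes between tissues was -0.0224 to 0.0569 with 1 cow left out, the highest without control cow 26, and 0.0818 without the 3 libraries that stand apart. Mammary against liver gave 11853 to 12420 genes with 1 cow left out. The 4 genes named in each tissue and the 3 named for the tissue difference kept their direction in every setting in which they were tested. These settings reuse the libraries in which the genes were chosen for a small p, so the constant direction gives no further support. The gene lists, the clock index and the composition covariates were not run because the 1 gene table available lists no Ensembl IDs. What depth alone limits was not tested; at the present depths edgeR recovered 0% of simulated 1.5-fold changes in either tissue, and DESeq2 26.5% in liver and 9% in mammary, with 18.5% and 33.3% of its calls false.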

Other observations

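The counts of splits for results of 0 genes, and the test for exchanged libraries, were chosen after the result was seen. For spread, overlap and unadjusted counts, the rule for reading the test was set before its result was seen. The overlap and unadjusted counts themselves were added after the data were examined. The 16 liver genes called by DESeq2 were more than most other splits of the cows gave: 2 of 100 splits, the real one included, gave as many, and the highest other split gave 18. This share was under 0.05, but it was not adjusted for the other counts tested by splits. With all libraries, edgeR in its main fit and limma-voom called 0 liver genes. Chance assignment of the cows is therefore not excluded for the DESeq2 count, which another split exceeded. Nor is it excluded for the 813 liver genes at unadjusted p under 0.05 in edgeR, since 19 of 100 splits gave as many and the highest other gave 1168. For counts of 0 past the edgeR threshold in liver, mammary and the tissue difference, all 100 of 100 splits necessarily give at least as many, which says nothing about chance; the highest other counts were 1, 180 and 57.

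Mammary splits showed a structure that is not the treatment. The 739 mammary genes at unadjusted p under 0.05 were reached by 53 of 100 splits, and the highest other split gave 3165, several times the real count. In 42 of the other splits phase shift cow 21 and control cow 26 fell on the same side, and these gave a mean of 1552 genes and at least 905. In the other 57, where they fell on opposite sides as in the real grouping, the mean was 522 genes, and 10 splits exceeded 739. All 10 splits with the highest counts had these cows on the same side. The real grouping, with 1 of them in each treatment, may therefore carry more unexplained spread than a grouping that unites them. For the tissue difference, 56 of 100 splits reached 1111 genes at unadjusted p under 0.05, and the highest other gave 2377.

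Genes whose treatment groups do not overlap were about as many as splits of the cows give. In liver 34 genes (0.247% of those tested) had every phase shift cow above or below every control cow, where chance gives 0.216%; 138 of all 462 splits gave as many and the highest other gave 83. In mammary 47 genes (0.302%) did so, 93 of 462 splits gave as many, and the highest other gave 374. Without the libraries that stand apart, the count was 62 in liver (chance 0.433%), reached by 165 of 462 splits, and 140 in mammary (chance 0.794%), reached by 33 of 126. The correlation of fold changes between tissues, 0.00146, was reached by 77 of 100 splits, with 0.126 as the highest other. Mammary against liver was different: 1 of 100 exchanges of tissue labels within cows gave as many as 12132 genes, and that was the real one, with 10961 as the highest other.

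A hypothesis that phase shifts increase the spread between cows was tested by the ratio of variances, phase shift over control. Its median over genes on the log2 scale was 0.29 in liver (exact permutation p = 0.773) and -0.033 in mammary (exact permutation p = 0.968). Without the libraries that stand apart it was -0.16 in liver and 0.39 in mammary (exact permutation p = 0.281 and 0.246). The hypothesis was neither borne out nor excluded, since the sign turned with 1 or 2 libraries and a p of 0.05 or more, set beforehand as evidence against it, excludes nothing in that case.

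Exchange of libraries between cows was argued against for the cows with both tissues, since 11 of 11 liver libraries correlated best with the mammary library of their own cow. In the other direction it was 10 of 11, since the mammary library of control cow 26 correlated at 0.261 with the liver of phase shift cow 23 and at 0.194 with its own. The liver library of phase shift cow 25 and the mammary library of phase shift cow 21, the labels found in 1 tissue each, correlated at 0.0774. This was below the lowest own-cow value of 0.178, but it was the highest among the mammary libraries for that liver, with 0.0572 next. For that mammary library, the livers of control cow 26 and phase shift cow 23 were higher, at 0.119 and 0.103. Whether these labels are separate cows or 1 cow named in different ways stays open, and the series describes 6 phase shift cows where the labels hold 7.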
